A study of Homo sapiens with 6 samples.

How the data were processed

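Bulk RNA sequencing was measured in 6 libraries labelled as PANC-1, an established human cell line derived from a pancreatic ductal carcinoma. Per the labels, 3 libraries came from cells with a short hairpin RNA against STN1 and 3 from cells with a control hairpin, each called a biological replicate. The genotype label of 2 of the shSTN1 libraries reads STN2 and STN3 knockdown, whereas their titles read shSTN1. The titles were used for grouping. Nothing further in the labels describes separate cultures, so the p-values measure the spread between these libraries, which may be technical in part. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the NEBNext Ultra kit.

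The authors deposited whole-number read counts per gene, without normalization, under Ensembl gene identifiers. Per the submitters' processing notes, the tools were cutadapt, FastQC, STAR 2.7.2b and featureCounts 2.0.1, with the genome build GRCh38. The annotation release and the strand setting of the counting are not given in the sources used here. Antisense and overlapping genes, and genes with near-identical copies such as metallothioneins, keratins, ribosomal proteins and histones, can therefore share or lose reads, and their values are uncertain to that extent. The table held 60668 rows, of which 45 were second copies of pseudoautosomal genes and were left out. Of the 60623 rows kept, 58516 were found in GENCODE 29 by identifier without its version, from which coordinates (GRCh38) and gene classes were taken.

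The comparison was fitted on these counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, library sizes were scaled by TMM factors, and the robust quasi-likelihood test gave the coefficient of shSTN1 minus control over all 6 libraries, without covariates. P-values were adjusted by Benjamini and Hochberg over the 17451 genes tested, with a threshold of 0.05. Levels are CPM computed with the TMM-scaled library sizes, as mean ± SD of 3 libraries. SEs are those of the difference between group means of log2 CPM (prior count 2), and do not come from the edgeR fit. The error of the carcinoma markers used this SE with a normal quantile. The interval of STN1 came from limma-voom (limma 3.58.1), and its exact permutation test was two-sided. For a gene without reads in a group, the fold was bounded with a floor of 3 reads over the 3 libraries of that group. With 1 to 3 reads, a 95% exact interval of the ratio was computed. Such bounds and intervals cover counting error only.

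Before the data were examined, 45 gene lists were fixed. Together with the embryonic kidney and carcinoma line markers described below, 1003 entries were matched to the table and 1 was left unmatched, SOD2. Lists with at least 5 tested members were compared with all other genes by limma's camera, with a preset correlation between genes of 0.01 and adjustment over the lists. The pancreatic acinar list had fewer tested members and was not run. The same test was applied to genes within 5 Mb of a chromosome end. Genes were named by a rule fixed at the same time. It took STN1, CTC1 and TEN1. It took the 12 highest and the 12 lowest log2 fold changes of protein-coding genes past the threshold, with at least 5 CPM in the higher group and no overlap between groups. From each list it took up to 4 members with the smallest adjusted p, or up to 2 as values where none passed. Other genes named were chosen after their values were seen, and are said to be so. Some genes that the rule takes are not reported here.

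Alternatives fixed beforehand were RLE and upper-quartile factors, 2 other low-count filters, protein-coding genes alone, the replicate number as a block, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, glmTreat against a fold of 1.2, camera with an estimated correlation, fry, other distances from chromosome ends, and leaving out each library. An alternative without genes at 3 or fewer reads over either group was added after the data were seen. Total counts ran from 17357223 to 23336942 per library. In simulated counts for this comparison (17109 genes run, 50 genes changed at each size), the test recovered 74% of genes changed 1.5-fold, 94% at 2-fold, 98% at 4-fold and 100% at 8-fold. Of its 188 calls, 2.66% were false. Few genes were changed in these simulated counts, so they do not show how scaling and false calls behave when most genes differ. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 3.02 to 8.89), so each counted as a separate library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample, and no column of values, was left out.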

Results

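Gene expression was compared between libraries labelled shSTN1 and control libraries, all labelled as PANC-1, to ask which transcripts differ when STN1 is targeted. STN1 is a subunit of the CST complex, which binds single-stranded DNA at telomeres and helps DNA polymerase alpha-primase fill in the complementary strand. The control libraries held 19549971, 20660453 and 17357223 counted reads, and the shSTN1-labelled libraries 22153769, 23336942 and 18813591. Reads fell on 26324 to 27296 genes per control library and on 25342 to 26021 genes per shSTN1-labelled library. Values after ± are SDs over 3 libraries.

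STN1 (ENSG00000107960.11, chromosome 10, positions 103882542 to 103918205 in GRCh38) did not differ beyond the spread between replicates. It had 387, 346 and 278 reads in the control libraries and 303, 306 and 275 in the libraries labelled shSTN1. The level was 16.4 ± 1.95 CPM in control and 14.8 ± 0.793 CPM in the shSTN1-labelled libraries, or 90.2% of control. The log2 fold change was -0.15 (SE 0.105, edgeR adjusted p = 0.253), with a limma-voom 95% interval of -0.38 to 0.09, which corresponds to 76.6% to 106% of control. The exact permutation test gave p = 0.3, where 3 libraries against 3 cannot go below 0.1. The measured STN1 mRNA therefore does not separate the labels, and every direction below is between libraries as labelled. The groups may hold different cells, as set out under the other observations, so no difference below is assigned to the hairpin. CTC1, the largest CST subunit, was higher in the shSTN1-labelled libraries, at 48.0 ± 3.10 against 36.7 ± 0.977 CPM (log2 fold change 0.39, edgeR adjusted p = 1.43e-04). TEN1 had 0 or 1 read in each library and was not tested.

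**Figure D1:**
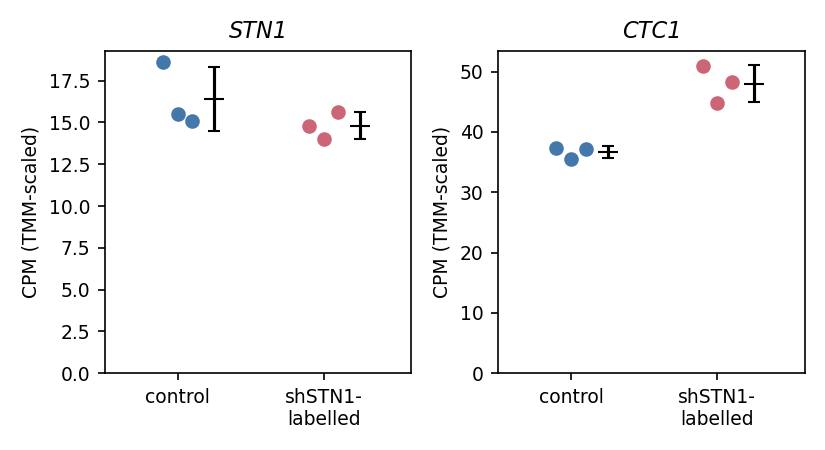
Level of STN1 and of CTC1 in CPM (vertical axis, TMM-scaled) in each control and each shSTN1-labelled library (points), with the mean and SD of 3 libraries (bar). The STN1 ranges overlap, with means of 16.4 and 14.8 CPM, while all 3 shSTN1-labelled libraries lie above the control libraries for CTC1.

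Most other genes did differ. Of 17451 genes tested, 12929 passed the edgeR adjusted p of 0.05 (74.1%), 6209 of them higher and 6720 lower in the shSTN1-labelled libraries. At least 2-fold differences were found for 6044 of these genes, 2734 higher and 3310 lower. The groups did not overlap for 13201 genes (75.6%), where chance gives 10%. Correlations of log2 levels were at least 0.99 within groups and 0.848 to 0.853 between them. The differences were not symmetric. Of the genes at 5 CPM or more in control, 56 had 0 reads over the 3 shSTN1-labelled libraries, whereas 0 genes at 5 CPM or more in the shSTN1-labelled libraries lacked reads in control.

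**Figure D2:**
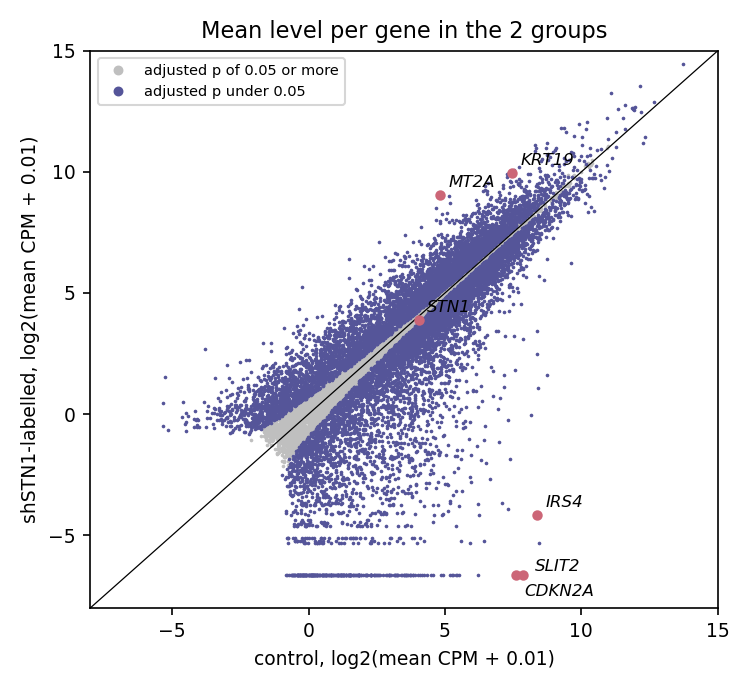
Mean level of each tested gene in the control libraries (horizontal axis) and in the shSTN1-labelled libraries (vertical axis), both as log2(mean CPM + 0.01) over 3 libraries, without XIST and Y-linked genes. Points on the line are equal in both groups, and the row of points at the bottom holds genes with 0 reads in the shSTN1-labelled libraries, such as SLIT2 and CDKN2A.

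Among the 12 genes most raised in the shSTN1-labelled libraries were metallothioneins, which bind zinc and copper, and secreted or matrix proteins. MT2A stood at 524 ± 35.6 against 28.0 ± 3.14 CPM (log2 fold change 4.23) and MT1E at 85.5 ± 7.95 against 2.77 ± 0.598 CPM (4.95). PTX3, a soluble pattern-recognition protein, had a log2 fold change of 4.12, and TNFRSF11B, which encodes osteoprotegerin, 4.65 from 0.78 CPM in control. The interstitial collagenase gene MMP1 (4.69), the gel-forming mucin gene MUC5AC (4.28) and the cytokine subunit gene EBI3 (3.99) started from under 1 CPM in control. The homeobox gene NKX6-2 had the highest value, 5.49 (SE 0.219), at 37.7 ± 1.58 against 0.840 ± 0.224 CPM. NCCRP1 (4.46, from 0.53 CPM in control), DNER (4.09, from 0.73 CPM) and SCUBE3 (4.05, from 4.12 CPM) were also in the group. NCCRP1 lies on chromosome 19 in a stretch where 28 of 30 genes at 5 CPM or more were at least 2-fold higher. The edgeR adjusted p of the genes named lay between 2.11e-29 for MT2A and 4.51e-14 for MUC5AC.

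The 12 genes most lowered were abundant in control and had nearly no reads in the shSTN1-labelled libraries. SLIT2, a secreted axon guidance ligand, had 14295 control reads (231 ± 23.1 CPM) and 0 reads in the shSTN1-labelled libraries, at least 4640-fold lower. CDKN2A, the locus of cell cycle inhibitors of the RB and p53 pathways, had 11753 control reads (192 ± 18.9 CPM) and 0 reads, at least 3810-fold lower. The insulin receptor adaptor gene IRS4 had 20505 reads against 3, a ratio of 6650 (95% interval 2280 to 32300). Developmental transcription factor genes formed part of this group, with at least 836-fold lower levels of HMX1 and 769-fold of SALL1. The transcriptional coactivator gene EYA4 was at least 582-fold lower. The protocadherin gene PCDH10 (at least 1480-fold), podoplanin gene PDPN (787-fold), IGFBP5 (729-fold) and TUSC3 (604-fold) also had 0 reads in the shSTN1-labelled libraries.

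Of 44 fixed gene lists that were run, 15 differed from the other genes by camera with the preset correlation, 9 higher and 6 lower in the shSTN1-labelled libraries. With an estimated correlation, 0 lists passed the adjusted p of 0.05, and 6 had an unadjusted p under 0.05. By fry, which does not compare a list with other genes, 36 lists passed. Counts of members adjusted over the list alone were equal to those over all genes, except for endocrine and neuroendocrine markers (12 against 11), nuclear oxidative phosphorylation (22 against 23), fatty acid synthesis (15 against 14) and mesenchymal identity (23 against 22). Since 74.1% of all genes passed, a count of members alone does not set a list apart.

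Epithelial genes were raised together in the shSTN1-labelled libraries, with 21 of 23 tested members higher, 1 lower and a median log2 fold change of 1.80. The camera adjusted p was 2.58e-07, and the adjusted p was 0.294 with an estimated correlation. Simple-epithelial keratin genes had the smallest edgeR adjusted p of the list, though not the largest fold changes. KRT8 stood at 3606 ± 66.8 against 606 ± 23.9 CPM, KRT18 at 965 ± 21.2 against 153 ± 5.12 CPM and KRT19 at 982 ± 10.4 against 175 ± 12.2 CPM. The desmosomal plakophilin gene PKP3 had a log2 fold change of 2.84. Integrins and laminins, which anchor cells to matrix, had 13 of 19 members higher and 3 lower (median 1.25, camera adjusted p = 3.11e-04, adjusted p = 0.294 with an estimated correlation), among them ITGA3 (2.22), ITGB5 (1.76) and ITGA5 (1.38). In the mesenchymal list 10 of 25 members were higher and 12 lower, and the list did not pass (camera adjusted p = 0.58). Its matrix genes TNC (-6.04) and SPARC (-5.06) and the transcription factor gene SNAI2 (-5.48) were lower, and S100A4 (3.12) was higher. These shifts lay between the same libraries that differ in CDKN2A, with 11753 against 0 reads. PANC-1 is described as lacking CDKN2A, so the cells of the groups may differ, and the shifts cannot be assigned to the hairpin.

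Inflammatory and growth factor response genes were higher in the shSTN1-labelled libraries. Of 19 NF-kB targets and cytokine genes, 18 rose and 1 fell, with a median of 2.64 (camera adjusted p = 1.34e-08, adjusted p = 0.117 with an estimated correlation). BIRC3, an inhibitor of apoptosis, reached 168 ± 17.9 from 11.6 ± 1.11 CPM, TNFAIP2 253 ± 12.2 from 28.2 ± 2.58 CPM, and the cytokine gene LIF 103 ± 5.10 from 12.1 ± 1.59 CPM. Genes that report MAPK/ERK output were higher in 15 of 18 cases and lower in 3 (median 1.66, camera adjusted p = 4.14e-06, adjusted p = 0.117 with an estimated correlation). Among them were the AP-1 subunit gene FOSL1 (3.24), EPHA2 (2.66), PHLDA1 (2.51) and IER3 (2.56), the last shared with the NF-kB list. YAP/TEAD targets had 16 of 20 members higher and 4 lower (median 1.01, camera adjusted p = 2.75e-04, adjusted p = 0.294 with an estimated correlation). NT5E (3.35), CCN1 (2.79) and AXL (2.74) rose, whereas FSTL1 fell (-3.46). Antigen presentation genes were higher in 11 of 15 cases and lower in 1 (median 1.36, camera adjusted p = 2.75e-04, adjusted p = 0.294 with an estimated correlation), with the immunoproteasome genes PSMB9 (3.16) and PSMB8 (3.01), the peptide transporter gene TAP1 (1.57) and TAPBP (1.82). The same libraries had 20505 against 3 reads of IRS4, so a difference in cells between the groups stays open for these lists too.

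**Figure D3:**
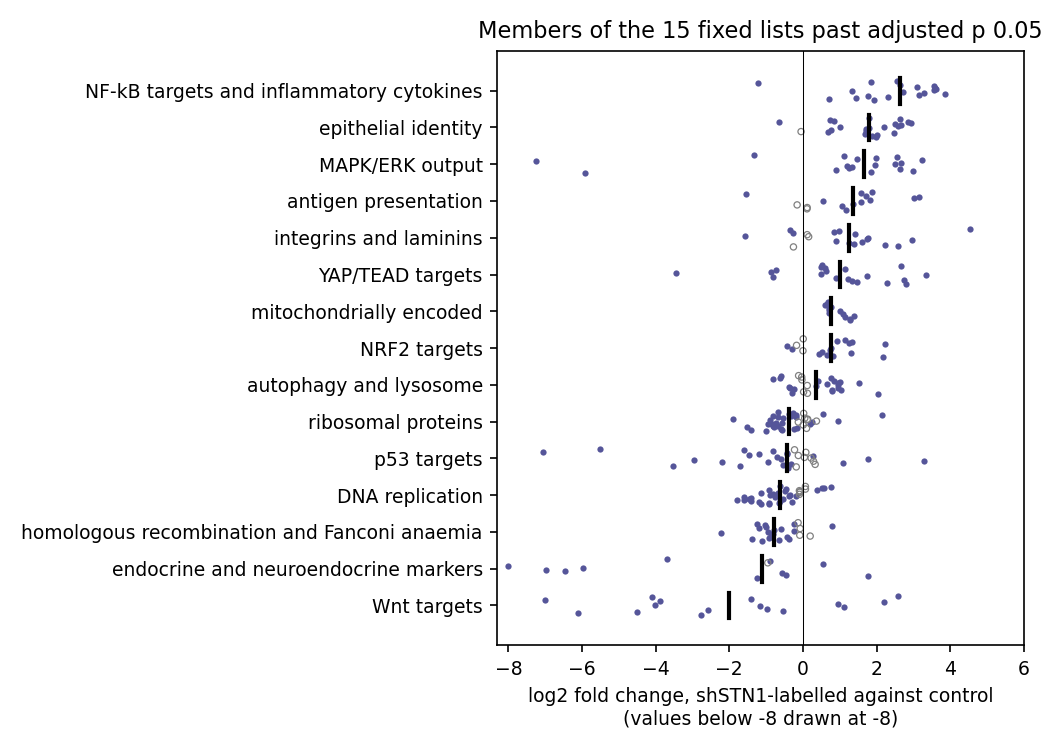
Log2 fold change, shSTN1-labelled against control, of each tested member (points, 1 row per list) of the 15 lists past the camera adjusted p of 0.05 with the preset correlation. Filled points passed the edgeR adjusted p of 0.05, open points did not, and the black bar is the median, from 2.64 for NF-kB targets to -2.0 for Wnt targets.

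All 13 mitochondrially encoded protein genes were higher in the shSTN1-labelled libraries, with a median of 0.77 (camera adjusted p = 2.58e-07, adjusted p = 0.294 with an estimated correlation). MT-ND4 had a log2 fold change of 1.38, MT-ND1 and MT-ND2 1.27 each, and MT-ND3 1.15. Mitochondrial genes took 7.84% to 8.28% of the reads of these libraries and 4.93% to 5.64% of the control reads. The nuclear genes of oxidative phosphorylation did not pass as a list (15 of 36 higher, 8 lower, median 0.12, camera adjusted p = 0.218). NRF2 targets, which serve antioxidant defence, were higher in 13 of 18 cases and lower in 2 (median 0.75, camera adjusted p = 0.0013, adjusted p = 0.294 with an estimated correlation). Among them were the quinone reductase gene NQO1 (2.17), TXNRD1 (1.31) and the ferritin genes FTL (1.34) and FTH1 (0.92). Autophagy and lysosome genes were higher in 14 of 27 cases and lower in 7 (median 0.36, camera adjusted p = 0.0371, adjusted p = 0.421 with an estimated correlation), among them the cargo receptor gene SQSTM1 (2.04) and the cathepsin genes CTSD (1.53) and CTSB (1.00).

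DNA replication genes were lower in the shSTN1-labelled libraries in 26 of 36 cases and higher in 4, with a median of -0.62 (camera adjusted p = 1.42e-04, adjusted p = 0.294 with an estimated correlation). The origin licensing factor gene CDT1 fell from 211 ± 16.8 to 61.6 ± 2.54 CPM, CDC45 from 117 ± 5.38 to 39.1 ± 1.59 CPM, and the helicase genes MCM2 and MCM6 had log2 fold changes of -1.13 and -1.19. Homologous recombination and Fanconi anaemia genes were lower in 18 of 23 cases and higher in 1 (median -0.77, camera adjusted p = 0.00161, adjusted p = 0.294 with an estimated correlation), with EXO1 at -2.22, RAD51C at -1.38, FANCD2 at -1.2 and FANCI at -1.03. Mitosis genes did not pass as a list (14 of 32 higher, 9 lower, camera adjusted p = 0.327), and ANLN (1.59) and CCNB1 (0.99) were among those raised. Of the 6 tested genes of CST and its partner polymerase, 2 were higher and 2 lower (camera adjusted p = 0.925). POLA1, the catalytic subunit of DNA polymerase alpha, fell from 50.8 ± 4.13 to 16.7 ± 1.13 CPM (log2 fold change -1.61, SE 0.0872, edgeR adjusted p = 3.78e-16), PRIM1 was at -0.39 and PRIM2 at 0.38. The shelterin and telomerase list, 4 of 16 higher and 9 lower, did not pass (camera adjusted p = 0.147), with TERF1 at -1.29, TERF2IP at -1.54, and NHP2 and NAF1 at -0.95 and -0.84. The cell cycle list of kinase inhibitors and G1 genes, 4 of 22 higher and 11 lower, did not pass (camera adjusted p = 0.373). In it CDKN2B had 298 reads against 0, at least 96.7-fold lower, and CCND2 (-5.20) and CCND1 (1.13) moved in opposite directions.

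Ribosomal protein genes were lower in 26 of 39 cases and higher in 5, with a median of -0.39 (camera adjusted p = 0.00545, adjusted p = 0.754 with an estimated correlation). RPS6 (-1.91), RPL13 (-1.51) and RPL5 (-1.42) fell, whereas RPS16 rose from 2198 ± 237 to 9805 ± 462 CPM (2.16). RPS6 lies on chromosome 9 within a window of 15 genes, from PSIP1 to ELAVL2. The median of that window, RPS6 included, was -1.91. RPS16 and the nucleolar methyltransferase gene FBL (1.86) lie on chromosome 19 within 1 Mb of AKT2, where 38 of the 50 tested genes besides these and AKT2 were higher and 10 lower. MYC fell (-1.32), and its list of ribosome biogenesis genes did not pass (6 of 27 higher, 15 lower, camera adjusted p = 0.165).

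**Figure D4:**
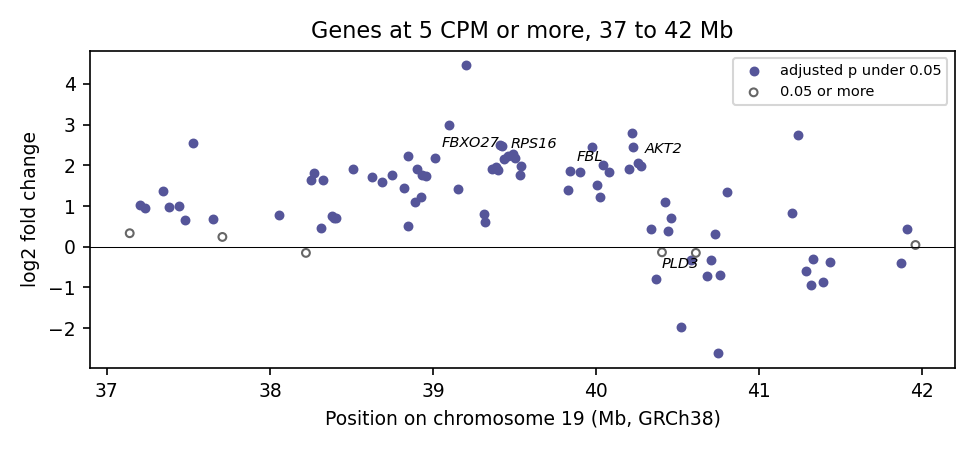
Log2 fold change, shSTN1-labelled against control (vertical axis), of genes at 5 CPM or more along chromosome 19 (horizontal axis, Mb in GRCh38). Filled points passed the edgeR adjusted p of 0.05 and open points did not. Most genes up to AKT2 are higher in the shSTN1-labelled libraries, RPS16 at 2.16 and FBL at 1.86.

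Wnt targets were lower in 12 of 16 cases and higher in 4 (median -2.0, camera adjusted p = 0.0371, adjusted p = 0.294 with an estimated correlation), with LEF1 at -4.02 and WNT5A at -4.11 but DKK1 at 2.20 and WNT7B at 2.58. The p53 targets were lower in 18 of 30 cases and higher in 4 (median -0.44, camera adjusted p = 0.0371, adjusted p = 0.294 with an estimated correlation). PMAIP1 (-3.53), BTG2 (-2.95) and SESN2 (-2.20) fell and PLK2 (3.30) rose. Endocrine and neuroendocrine markers were lower in 9 of 12 cases and higher in 2 (median -1.10, also with the gene without reads at its bound, camera adjusted p = 0.0431, adjusted p = 0.395 with an estimated correlation). INSM1 had 810 reads against 0, at least 263-fold lower, and NCAM1 (-6.45), PAX6 (-5.98) and ISL1 (-3.69) were lower. With protein-coding genes alone, Wnt targets had a camera adjusted p of 0.0556, and p53 targets and the endocrine list 0.061 each. The endocrine list was also lost without genes at 3 or fewer reads (adjusted p = 0.12), without control replicate 3 (0.0535) and without shSTN1 replicate 2 (0.0524).

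The leukocyte, endothelial and pancreatic ductal marker lists did not pass. Leukocyte markers were higher in 3 of 6 cases and lower in 2 (camera adjusted p = 0.796), with CORO1A at 16.8 ± 1.84 CPM in the shSTN1-labelled libraries and 12 ± 1.61 CPM in control. Endothelial markers were higher in 2 of 5 cases and lower in 2 (camera adjusted p = 0.987), with FLT1 at 15.3 ± 2.14 CPM in control and 0.120 ± 0.0437 CPM in the shSTN1-labelled libraries. Ductal markers were higher in 7 of 11 cases and lower in 4 (camera adjusted p = 0.147). AGR2 (2.23) and ANXA4 (2.00) rose, and the carbonic anhydrase gene CA2 fell from 340 ± 13.4 to 2.11 ± 0.471 CPM. Of the acinar markers, NR5A2 stood at 10.0 ± 0.697 against 5.39 ± 0.296 CPM.

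Genes within 5 Mb of chromosome ends were examined because STN1 acts at telomeres. Of 2438 such genes, 1111 were higher and 690 lower in the shSTN1-labelled libraries, with a median log2 fold change of 0.22 against -0.07 for the other genes. The set passed by limma camera with the preset correlation (p = 0.00416). It did not pass with an estimated correlation (p = 0.285).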

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

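The alternative without genes at 3 or fewer reads was chosen after the data were seen. Counts of genes past the threshold ran from 10981 (protein-coding genes alone) to 13901 (no low-count filter) over the alternatives with the adjusted p of 0.05, with 12911 under upper-quartile factors, 12450 by DESeq2 and 12917 by limma-voom, and 11619 at an adjusted p under 0.01. The 2-fold counts ran from 4581 to 7348. Lists past the threshold numbered 0 with an estimated correlation and 36 by fry, against 15. With no low-count filter 22 of 45 lists passed, and with protein-coding genes alone 12 of 44. The telomere-proximal p became 0.285 with an estimated correlation and otherwise stayed at or under 0.0293. Leaving out 1 library at a time gave 12586 to 12857 genes, 6251 to 6299 at 2-fold, 14 to 16 lists, an STN1 log2 fold change of -0.22 to -0.06, and a telomere-proximal p of 0.0018 to 0.00894. The replicate block gave 12742 genes, 6014 at 2-fold, 15 lists, an STN1 value of -0.15 and a telomere-proximal p of 0.0042. Deviations of libraries with the same number correlated at -0.0491, 0.0778 and -0.061, so the numbers do not pair the libraries. Of the 12742 genes called with the block, 12710 were also called without it, and no call of a list or a named gene changed. STN1 passed the threshold under none of the alternatives run. List directions reversed only far from the threshold. The hypoxia list turned with no filter (adjusted p = 0.974), the block (0.995), protein-coding genes (0.969), and without control replicate 3 (0.936) or shSTN1 replicate 2 (0.856) or 3 (0.948), within 0.748 to 0.999 over left-out libraries. The endothelial list turned with upper-quartile factors (0.978), no filter (0.825), without control replicate 2 (0.975) and without shSTN1 replicate 2 (0.954), within 0.936 to 1, and the RNA interference list without control replicate 2 (0.811, within 0.77 to 0.971). The cause was not tested. The 198 named genes tested kept direction wherever they were tested, with at most 2 losing their call in any 1 left-out library. Depth limits the genes without reads, whose folds are bounds.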

Other observations

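The tests of STN1 knockdown size, constant admixture, index exchange and CDKN2A in control were chosen after the results they measure were seen, as were the HOX genes, the chromosome 9 and 19 regions and the genes MTAP, CDKN2B-AS1, AL359922.2, TUBB8P1, IL1RL1 and MIR3142HG. HOX genes, which encode positional transcription factors, were not a fixed list, and no test compared their clusters. Their counts stand beside the 74.1% of all tested genes that passed. In the HOXA cluster 9 of 11 tested genes were lower in the shSTN1-labelled libraries, 7 of them at least 8-fold, and in the HOXD cluster 7 of 8 were lower. HOXA10 stood at 59.1 ± 0.567 CPM in control and 0.474 ± 0.153 CPM in the shSTN1-labelled libraries, and HOXD10 at 49.8 ± 3.44 and 0.0993 ± 0.0834 CPM. HOXD13 had 9709 reads against 3. In the HOXB cluster 7 of 9 genes were higher, such as HOXB3 at 203 ± 7.16 against 70.2 ± 8.23 CPM, while HOXB9 (-0.77) and HOXB13 (-0.45) were lower. Of 8 HOXC genes, 5 were higher and 2 lower.

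Other fixed lists held strong changes in both directions and did not pass as lists. Interferon-stimulated genes were higher in 18 of 30 cases and lower in 8 (camera adjusted p = 0.0695), with OAS3 at 2.49 and MX2 at 2.11 but BST2 at -5.89. Among matrix proteases and inhibitors, 10 of 19 higher and 8 lower, the urokinase gene PLAU rose from 35.7 ± 1.80 to 510 ± 12.1 CPM, whereas ADAMTS1 fell from 284 ± 13.3 to 0.951 ± 0.23 CPM and TIMP3 from 47.6 ± 1.86 to 0.265 ± 0.0341 CPM. TGF-beta response genes were higher in 11 of 21 cases and lower in 7, with LTBP2 at 2.46 and ID2 at -2.29. In the Notch list, 6 of 16 higher and 7 lower, HEY1 (-4.75) and JAG1 (3.03) moved apart, and in the glycolysis list, 6 of 19 higher and 7 lower, the lactate transporter genes SLC16A3 (2.64) and SLC16A1 (-1.64) did. Of 29 axon guidance genes, 11 were higher and 17 lower, with UNC5B at -6.02 and SEMA4B at 2.53. The serine synthesis gene PHGDH (-2.75) and GDF15 (2.57) belong to the ATF4 list, 5 of 26 higher and 13 lower. The 29 lists that did not pass had camera adjusted p from 0.0695 to 0.987. The median, the mean and the test differed in sign for 8 lists: calcium and potassium channels (median 0.54, mean -0.18), matrix proteases (0.42 and -0.36), cholesterol synthesis (0.03 and -0.13), leukocyte markers (0.37 and -0.06), CST and its polymerase (0.02 and -0.20), RNA interference (0.08 and -0.06), endothelial markers (0.59 and -1.34), and circadian genes (median -0.10, test upward).

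Most genes differed between the groups while STN1 hardly did. A knockdown of STN1 mRNA by at least 50% within a single cell line is argued against by the lower bound of the log2 interval, -0.38. Control libraries made wholly of PANC-1, a line described as lacking CDKN2A, are argued against by their 11753 CDKN2A reads. The choice among scaling factors is argued against by the 12911 genes that passed under upper-quartile factors (12704 of them also under TMM). All these factors scale a whole library by 1 value, so an error that they share would not be seen in this way. A control from another line, of embryonic kidney type, stays open as a hypothesis, since 2 of 5 markers listed before their values were seen were at least 8-fold higher there (NEFL 389-fold and LIN28B 11.6-fold, but CKB 3.46-fold, ZIC2 1.57-fold and PAX2 lower). For a control nearly free of carcinoma cells, all 7 carcinoma markers were lower there, 1 of them by at least 4-fold (S100A6, 7.89-fold). This count met the bound set beforehand against the explanation, fewer than 2, and fell short of the count set in its favour. The bound is not held to here, because ANXA2 (3.92-fold) and CD44 (3.91-fold, 434 ± 10.3 CPM in control) lay within their error of 4-fold. A control nearly free of carcinoma cells therefore also stays open. Effects of the hairpin that do not show in STN1 mRNA were not tested and stay open, because the label and the cell population may change together, and if the populations differ, the STN1 ratio says nothing about the knockdown.

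Neighbouring genes on chromosomes 9 and 19 differed together, but this was not particular to these chromosomes. Over 11686 genes, log2 fold changes of neighbours had a Spearman correlation of 0.257, against at most 0.0311 in 1000 shuffles. Among windows of 15 genes, the largest median was on chromosome 7, from HOXA2 to CPVL (-3.19). The window from PSIP1 to ELAVL2 around CDKN2A had a median log2 fold change of -1.91. Chromosome 19 had windows from FBXO27 to DLL3 (2.19) and from EID2B to AC118344.1 (1.91). These windows on chromosomes 7, 9 and 19 exceeded in size the largest window median in 100 shuffles, 1.84. Windows on chromosomes 13 (-1.65) and 8 (-1.54) were also among the largest but did not exceed it. Nearer to CDKN2A, within 1 Mb, 6 of 12 other tested genes were lower and 5 higher. On chromosome 19, the median log2 fold change of the tested genes within 1 Mb of AKT2, without AKT2, FBL and RPS16, was 1.5 (50 genes, -2.62 to 2.80), which is consistent with a gain of copies there in the cells of the shSTN1-labelled libraries, as a hypothesis from RNA alone. Between positions 38990714 and 40285536, limits chosen after the values were seen, 28 of 30 genes at 5 CPM or more were at least 2-fold higher. For a deletion around CDKN2A, the test set beforehand found 0 of 3 other genes at 5 CPM or more in control with 3 or fewer reads in the shSTN1-labelled libraries, which by the bound written in advance would speak against it. That bound is not held to here because CDKN2B, at 4.87 CPM just under its limit, had 298 reads against 0. MTAP had 3108 against 40, and the antisense genes CDKN2B-AS1 214 against 0 and AL359922.2 70 against 0. The 5 higher genes all lay outside this stretch (21802543 to 22121097), but the untested pseudogene TUBB8P1 lay inside it at 15 against 29. From these reads, a small deletion cannot be told apart from silencing of the locus. PANC-1, the line on the label, is described as lacking CDKN2A, so the absence of its reads need not stem from the hairpin.

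No abundant transcript of the shSTN1-labelled libraries was missing from control, while many control transcripts were missing from the shSTN1-labelled libraries: of genes at 50 CPM or more in 1 group, 0 of 4538 and 29 of 4483 lay under 1% of that level in the other group. A constant admixture of shSTN1-like RNA in the control libraries cannot be told apart from expression by the control cells. The 50 lowest genes picked in control replicate 1 had a median of 11.7% in the other control replicates. With a lowest mean of 3.24% among the 4538 genes, this value had to pass its bound of 1% and gives no support. Apart from sampling error, an admixture equal for all genes could not exceed that lowest mean. Below that abundance, IL1RL1 (1 read against 176, 0.553%, 95% interval 0.0139% to 3.12%) and MIR3142HG (4 against 390, 0.998%, 95% interval 0.271% to 2.58%) have too few reads to decide on a smaller share. For exchange of index reads among these libraries, the upper limit of SLIT2 in the shSTN1-labelled libraries was 0.0216% of control. SLIT2 was picked after it was seen to have 0 reads there, so the limit is the floor of 3 reads. It argues only against reads passing from control to the shSTN1-labelled libraries. Passage the other way, which this pattern would need, is not covered by this limit and stays open. If equal for all genes, it too could not exceed about 3.24%. The test replaced an earlier one whose value, 0.638%, fell between its bounds. A marked difference of this share between control libraries is argued against by correlations of at most 0.0736 in size between a library's deviations and the fold changes. How small a difference would be seen in this way was not measured, so a small one stays open.

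The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. Each of the other splits puts libraries of both labels in both groups. The label difference then widens the spread within groups, so low gene counts there could be foreseen. The other splits also still hold part of the label difference. Their values therefore do not show what chance alone gives. The real split gave 12929 genes and 6044 at 2-fold, as many as 1 of the 10 splits, and the highest of the others gave 0 by edgeR, with 22 to 43 genes at an unadjusted p under 0.05. For lists, 2 of the 10 splits gave at least the real count of 15, and the highest of the others also gave 15. For telomere-proximal genes, 4 of the 10 splits gave a p as small as 0.00416, the smallest of the others being 2.01e-05.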
